A study of Homo sapiens with 30 samples.

How the data were processed

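RNA was measured by sequencing in UMUC1, an established human bladder cancer cell line that, per the series record, carries a loss-of-function mutation of UTX, the protein of the gene KDM6A. There were 2 experiments with 10 groups and 30 samples, 3 per group. The first compared an empty vector (EV), wild type UTX and a UTX with the changes H1146A and E1148A (HEAA) in full medium (MEM with 10% fetal bovine serum) and in sphere medium. Sphere medium was serum-free MEM with B27 without vitamin A, FGF2 at 20 ng/ml and EGF at 20 ng/ml. The second compared EV and UTX in cells that carried a vector for wild type FGFR3 or for FGFR3 with S249C, a mutation found in bladder cancer. Per the labels the vectors were pSIN-puro in the first experiment, and pBabe-puro for FGFR3 and pCDH-blasticidin for UTX in the second. RNA was harvested on day 3 and extracted with Qiagen RNeasy, and libraries were made with Illumina TruSeq in the first experiment and NEBNext Ultra II RNA in the second, per the labels. The labels number the replicates 1 to 3 without saying whether these were separate cultures, so p-values measure the spread between these samples, which may be technical.

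The values were estimated counts per gene (expected counts) that the authors deposited as whole numbers, not scaled to library size. The processing notes name Salmon 0.8 for quantification, DESeq2, and the builds hg19 and GRCh37. The step from transcripts to genes and the annotation release are not given in the sources used here. The first table held 58288 genes, of which 16276 were at 0 in all 18 libraries. The second held 20073 genes, of which 3 were at 0 in all 12 libraries, and 457 of its genes had at least 10 counts in fewer than 3 libraries, so it had passed a filter that is not given in the sources used here. Between 99.23% and 99.52% of each library's counts in the first table lay in genes of the second. Of the versioned gene IDs, 95.49% in the first table and 40.52% in the second were in GENCODE v29. Positions are those of GENCODE v29 on GRCh38, which is not the build the notes name. Gene names came from the files for 26160 and 15696 genes and from a reference table for 16441 and 1402 genes, which left 15687 and 2975 IDs without a name.

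Each experiment was fitted on its own with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, 1 mean per group, a dispersion trend over mean level, and quasi-likelihood F tests with Benjamini-Hochberg adjustment. Adjusted p under 0.05 was the threshold. The filter left 19629 and 19399 genes, with common biological coefficients of variation of 4.6% and 6% and prior degrees of freedom of 8.5 and 6.7. Levels are library-scaled counts (CPM) with TMM factors, as mean ± SD with n = 3 libraries. Log2 fold changes are given ± SE, taken as the size of the fold change over the square root of F. An interaction is the difference between 2 log2 fold changes. A gene was called separated when all 3 libraries of 1 group lay above all 3 of the other, which chance alone gives for 10% of genes. Total counts per library were 23749352 to 40111234 in the first experiment and 21672408 to 28290664 in the second. Where a group held 0 counts of a named gene, the fold is a lower bound from a floor of 3 counts over the group, and where it held 1 to 3 counts the ratio has a 95% counting interval. These intervals and floors cover counting error only.

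The 24 gene lists held luminal markers (without FGFR3), basal markers, squamous and cornified envelope genes, feedback and target genes of FGFR and MAPK signalling, mesenchymal genes, epithelial junction genes, mitosis genes, DNA replication genes, interferon-stimulated genes, NF-kB targets and cytokines, cholesterol synthesis, fatty acid synthesis, PPAR targets, hypoxia and glycolysis, YAP and TGF-beta targets, retinoid genes, stress response, the KMT2C/KMT2D complex without KDM6A, PRC2 with KDM6B, HOX genes, fibroblast markers, leukocyte and endothelial markers, mitochondrial RNA and ribosomal proteins. Each was tested against all other genes with camera from limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The test was run again with the correlation estimated from the data. The lists, the comparisons, the alternatives and the rule for named genes were chosen before the data were examined. Of 384 list tests, 155 passed with the preset correlation and 30 with the estimated one, and all 30 passed both ways. In 51 of the 384 tests the median or mean of a list differed in sign from the test, and 2 of these passed.

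The genes named were KDM6A in every comparison and FGFR3 in the second experiment. In 6 main comparisons (UTX against EV in each medium and with each FGFR3, sphere against full medium in EV, and S249C against wild type FGFR3 in EV) they were also the 5 largest rises and 5 largest falls. These came from genes past the threshold with a mean of at least 2 CPM over the 2 groups, separated samples and an approved-style symbol. Up to 3 members with the smallest adjusted p came from each list that passed camera, and always from the luminal, basal and FGFR and MAPK lists. Other comparisons named 3 rises and 3 falls. A gene named for 1 comparison could be given values in another.

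Log2 fold changes of 2 comparisons were correlated across genes, with p from 100000 permutations of gene pairings, and calls were counted by direction against the number expected from the margins. This was done for 8 pairs of comparisons. The pairs of the UTX effect in full medium with the S249C effect and with the UTX effect beside wild type FGFR3 were chosen before the data were examined, and the other pairs later. Where comparisons shared controls, r and covariance from sharing alone were simulated in 20 draws.

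The fit was tested on simulated data. With known changes added to libraries like those of UTX and EV in full medium, it recovered 73.1%, 97% and 100% of changes of log2 0.5, 1 and 2, with 12 false calls (6.2% of calls). For S249C against wild type FGFR3 the shares were 64.2%, 91% and 100%, with 10 false calls (5.6%). Replicates varied by more than counting error, with 2.08 to 13.19 for chi-square per degree of freedom over 30 replicate pairs. The first 2 principal components held 65.3% and 11.7% of the variance in the first experiment and 24.9% and 14.7% in the second. Alternatives were DESeq2 1.42.0, median-of-ratios (RLE) factors, no low-count filter, a filter at 5 CPM, the replicate number as a block, only the groups compared, and each replicate left out in turn. Leaving out both EV_FGFR3S249C replicate 1 and UTX_FGFR3S249C replicate 3 was added after the data were seen. Tables were written with Python 3.11.15 and numpy 2.4.6, and figures with matplotlib 3.10.9.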

Results

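Gene expression was measured by RNA sequencing in 30 samples of UMUC1 bladder cancer cells, in 2 experiments with 3 libraries in each of 10 groups. The question, as the series record states it, was how restored UTX, a histone H3K27 demethylase encoded by KDM6A, and active FGFR3, a receptor tyrosine kinase, act on differentiation genes. In full medium the total counts were 27425684, 33069360 and 39415722 for the empty vector (EV_full), 32633665, 23817093 and 29365680 for UTX (UTX_full) and 26392441, 25623028 and 30029477 for the double mutant HEAA (HEAA_full). In sphere medium they were 33324042, 31305529 and 34305388 for EV_sphere, 25743116, 24085922 and 23749352 for UTX_sphere and 40111234, 24250265 and 31682124 for HEAA_sphere. With wild type FGFR3 they were 23107255, 26051649 and 25459186 for EV_FGFR3WT and 23309180, 21672408 and 25802360 for UTX_FGFR3WT. With S249C they were 25482269, 25078177 and 25987170 for EV_FGFR3S249C and 27537079, 27853116 and 28290664 for UTX_FGFR3S249C. Levels below are CPM, mean ± SD, n = 3 libraries per group, and log2 fold changes are ± SE from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment.

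KDM6A (ENSG00000147050, chromosome X, 44873177 to 45112602 on GRCh38) separated the groups as the vectors did. In full medium it stood at 17.4 ± 0.745 CPM in EV, 579 ± 12.7 in UTX and 694 ± 7.34 in HEAA. In sphere medium the levels were 8.18 ± 0.784, 861 ± 14.9 and 943 ± 15.3 CPM. In the second experiment KDM6A was at 15.8 ± 1.02 CPM in EV and 824 ± 73.2 in UTX with wild type FGFR3, and at 11.6 ± 1.36 and 862 ± 141 with S249C. These counts do not separate vector RNA from RNA of the cells' own gene.

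**Figure D1:**
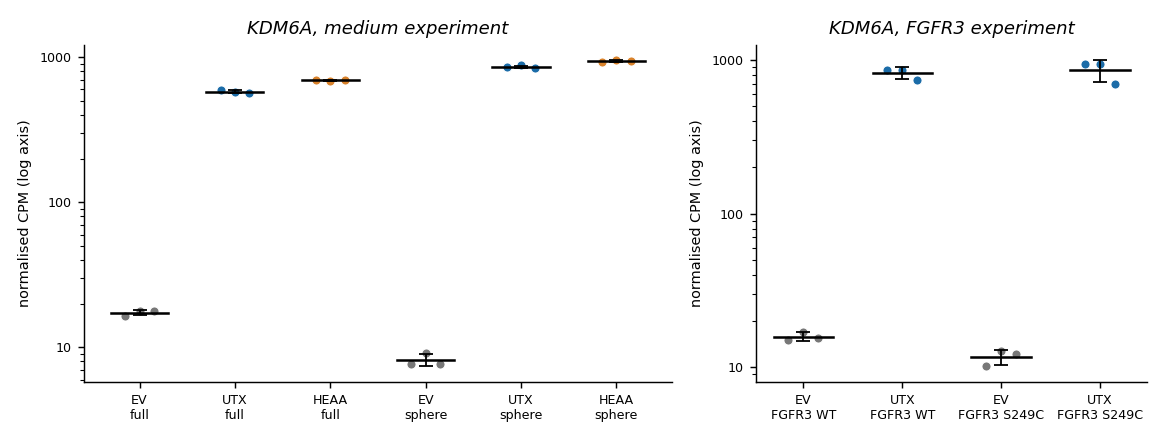
KDM6A level in CPM on a log axis in the 10 groups, with 1 point per library and the mean ± SD of 3 libraries. EV in full medium was at 17.4 ± 0.745 CPM and UTX in full medium at 579 ± 12.7.

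The first comparison asked what wild type UTX changed in full medium. KDM6A rose (log2 fold change 5.05 ± 0.05, adjusted p = 1.53e-25). KRT5 (ENSG00000186081, chromosome 12, 52514575 to 52520687), a keratin of basal urothelial cells, fell from 2287 ± 96.5 to 167 ± 9.37 CPM (log2 fold change -3.77 ± 0.06, adjusted p = 3.96e-22). KRT6A, a keratin of activated squamous epithelium, fell from 536 ± 21.1 to 79.5 ± 5.11 CPM, and the desmosomal cadherin DSC3 from 116 ± 3.6 to 25.1 ± 2.05 CPM (adjusted p = 7.52e-21 and 1.38e-18). The calcium-binding protein S100A9 of inflamed epithelium fell from 329 ± 6.57 to 5.54 ± 0.87 CPM, a 59.9-fold change (adjusted p = 3.86e-25). KRT1, a keratin of cornifying skin, was at 0.1 ± 0.02 CPM against 46.8 ± 2.56 (adjusted p = 3.76e-18). S100A8, the partner of S100A9, was at 0.09 ± 0.06 against 20.5 ± 2.28 CPM (log2 fold change -7.80, adjusted p = 2.89e-18). The desmoglein DSG1 had 0 counts in UTX and 517 in EV, at least 153-fold lower (adjusted p = 1.84e-13). The serpin SERPINB3 had 0 and 443 counts, at least 131-fold lower (adjusted p = 1.14e-12). The elastase inhibitor PI3 had 2 and 668 counts, a ratio of 297 (95% counting interval 82 to 2460, adjusted p = 1.59e-13).

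Among the largest rises in UTX, the gap junction gene GJA5 went from 5.9 ± 0.41 to 126 ± 1.95 CPM (log2 fold change 4.42 ± 0.06, adjusted p = 1.07e-22). The basement membrane gene FRAS1 was at 6.2 ± 0.75 against 0.07 ± 0.06 CPM (log2 fold change 6.25, adjusted p = 4.58e-13). The microfibril gene MFAP5 was at 16.1 ± 0.56 against 0.91 ± 0.3 CPM (log2 fold change 4.11, adjusted p = 1.97e-15), and the metalloprotease gene TLL2 at 5.12 ± 0.2 against 0.31 ± 0.14 CPM (log2 fold change 4.02, adjusted p = 3.04e-13). Of the luminal list, 13 of 31 were higher and 9 lower (14 and 9 adjusted over the list alone, camera adjusted p = 0.287, adjusted p = 0.71 with an estimated correlation), and the list did not pass. Its median was 0.16 and its mean -0.22. In that list KRT13 fell from 2489.9 ± 50.3 to 1102 ± 24.5 CPM (adjusted p = 4.54e-17). GRHL3, a transcription factor of surface epithelium, fell from 20.4 ± 1.13 to 2.19 ± 0.31 CPM (adjusted p = 1.01e-17). The surface protein CD24 rose from 27.8 ± 0.71 to 79.8 ± 5.85 CPM (adjusted p = 2.47e-16). Basal genes moved in both directions: 11 of 22 were higher and 9 lower (11 and 9 adjusted over the list alone), with a median of 0.18, a mean of -0.35 and camera adjusted p = 0.675.

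Squamous and cornified envelope genes were lower in UTX: 1 of 20 was higher and 13 lower (1 and 13 adjusted over the list alone), with a median log2 fold change of -2.54, or -3.35 without 3 genes at or under the floor in both groups and with other counts of 0 set to the floor (camera adjusted p = 0.00733, adjusted p = 0.284 with an estimated correlation). All measured DNA replication genes fell: 0 of 20 were higher and 20 lower (0 and 20 adjusted over the list alone) and a median of -0.98 (camera adjusted p = 3.72e-15, adjusted p = 0.144 with an estimated correlation). MCM3 and MCM6 of the replicative helicase fell from 175 ± 0.66 to 84 ± 0.95 CPM and from 174 ± 3.24 to 72.8 ± 2.74 CPM, and the licensing factor CDC6 from 95.8 ± 2.06 to 42.4 ± 1.2 CPM (adjusted p = 2.47e-16, 4.54e-16 and 1.67e-16). Of the mitosis list, 3 of 20 were higher and 7 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.651). Of the cholesterol synthesis genes, 0 of 24 were higher and 19 lower (0 and 19 adjusted over the list alone), median -0.45 (camera adjusted p = 1.85e-07, adjusted p = 0.144 with an estimated correlation). CYP51A1 fell from 144 ± 3.17 to 76.9 ± 3.16 CPM, and ACAT2 and FDPS had log2 fold changes of -0.74 and -0.62 (adjusted p = 1.27e-14, 3.3e-12 and 8.02e-12). Of the fatty acid synthesis genes, 2 of 16 were higher and 12 lower (2 and 12 adjusted over the list alone), median -0.42 (camera adjusted p = 0.000314, adjusted p = 0.144 with an estimated correlation). The desaturase SCD fell 3.51-fold, to 89.2 ± 2.11 CPM (adjusted p = 3.45e-19), and the lipid regulator SREBF1 fell from 100.8 ± 6.3 to 50.4 ± 1.18 CPM (adjusted p = 2.61e-13).

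YAP and TGF-beta targets were mostly higher in UTX: 16 of 20 were higher and 2 lower (16 and 2 adjusted over the list alone), median 0.59 (camera adjusted p = 3.09e-07, adjusted p = 0.144 with an estimated correlation). AMOTL2 rose from 258 ± 4.57 to 525 ± 2.45 CPM and PMEPA1 from 167 ± 0.64 to 466 ± 10.9 (adjusted p = 3.75e-14 and 3.72e-13). Of the fibroblast markers, 5 of 9 were higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.0343, adjusted p = 0.255 with an estimated correlation). The camera call was lost without EV_full replicate 3 (adjusted p = 0.0617) or UTX_full replicate 2 (adjusted p = 0.0559). They were low: the collagen COL1A1 was at 8.2 ± 0.6 against 5.31 ± 0.56 CPM (adjusted p = 6.17e-06), the protease FAP at 1.17 ± 0.07 against 0.26 ± 0.05 CPM (adjusted p = 1.13e-05), and POSTN had 64 counts against 0, at least 24-fold higher (adjusted p = 1.69e-06). Every listed ribosomal protein gene fell: 0 of 30 were higher and 30 lower (0 and 30 adjusted over the list alone), median -0.54 (camera adjusted p = 7.23e-15, adjusted p = 0.27 with an estimated correlation). RPS3 fell from 1717 ± 65.2 to 1094 ± 60.3 CPM and RPL27 from 576 ± 27.4 to 347 ± 13.0 CPM (adjusted p = 1.38e-11 and 2.26e-12). RPL and RPS genes held 6.22% of EV_full and 4.40% of UTX_full counts.

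The other lists did not pass in full medium. Of the FGFR and MAPK genes, 7 of 26 were higher and 14 lower (7 and 14 adjusted over the list alone, camera adjusted p = 0.0943). The phosphatase DUSP6 fell from 23.9 ± 1.55 to 7.33 ± 0.27 CPM, the transcription factor ETV4 from 13.3 ± 0.19 to 2.62 ± 0.33 CPM and EMP1 from 664 ± 6.02 to 263 ± 12.3 CPM (adjusted p = 1.19e-15, 3.44e-15 and 1.64e-16). Of the mesenchymal genes, 7 of 15 were higher and 3 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.162). Among junction genes, 9 of 23 were higher and 7 lower (10 and 8 adjusted over the list alone, camera adjusted p = 0.792). Of the interferon-stimulated genes, 6 of 22 were higher and 8 lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.651). Among NF-kB targets and cytokines, 4 of 16 were higher and 6 lower (4 and 7 adjusted over the list alone, camera adjusted p = 0.734). Of the PPAR targets, 5 of 16 were higher and 6 lower (5 and 6 adjusted over the list alone, camera adjusted p = 0.76). Among hypoxia and glycolysis genes, 7 of 23 were higher and 8 lower (8 and 8 adjusted over the list alone, camera adjusted p = 0.984). Of the retinoid genes, 3 of 13 were higher and 4 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.977). Among stress response genes, 10 of 20 were higher and 5 lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.162). Of the KMT2C/KMT2D complex genes, 3 of 9 were higher and 5 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.287). Among PRC2 with KDM6B, 4 of 12 were higher and 7 lower (4 and 8 adjusted over the list alone, camera adjusted p = 0.287). Of the HOX genes, 3 of 25 were higher and 10 lower (3 and 10 adjusted over the list alone, camera adjusted p = 0.324). Of the leukocyte and endothelial markers, 3 of 8 were higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.86). Among mitochondrial RNA, 2 of 13 were higher and 3 lower (1 and 3 adjusted over the list alone, camera adjusted p = 0.882). By edgeR, 5583 genes were higher and 5736 lower, 1412 and 666 of them by at least 2-fold, and 12478 genes (63.6%) were separated, where chance gives 10%.

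**Figure D2:**
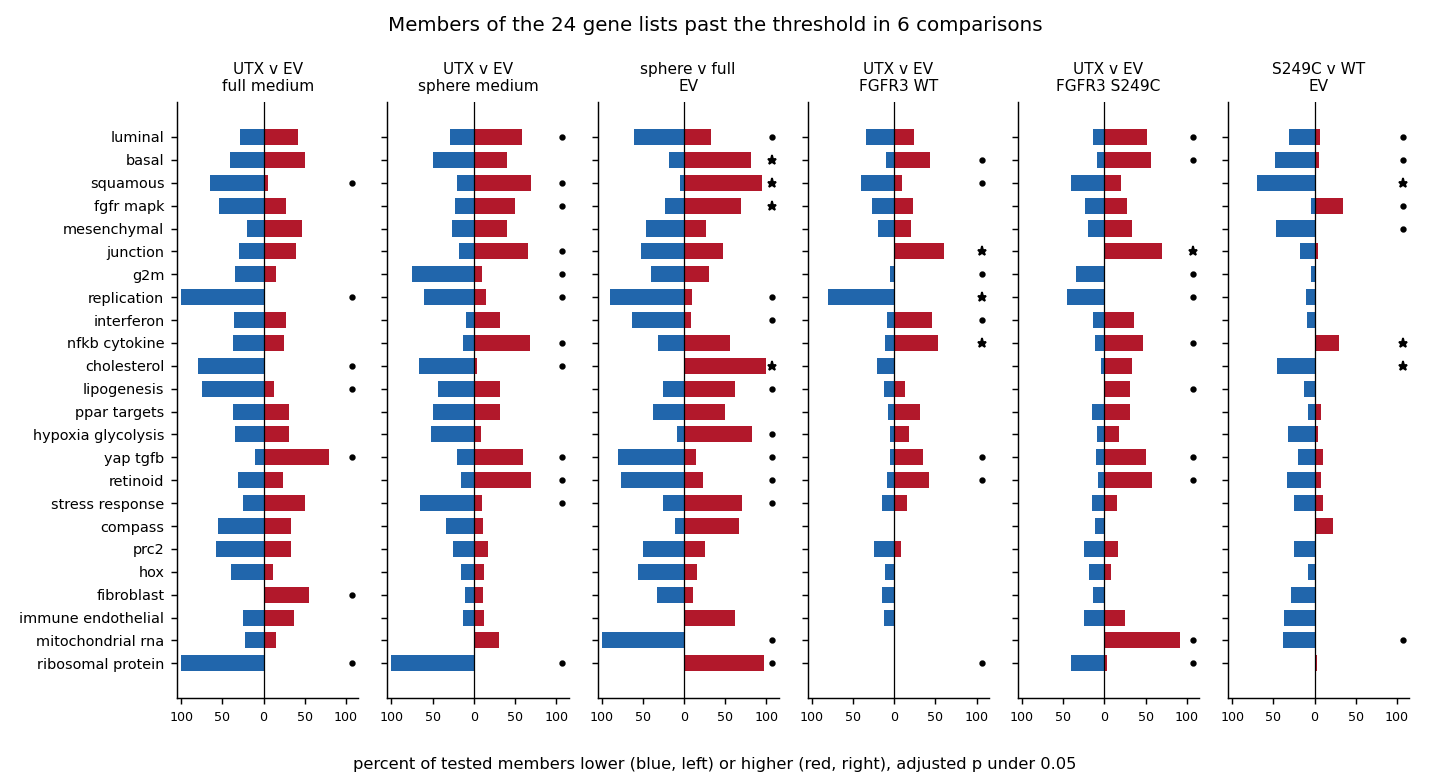
Percent of each list's genes higher and lower past the threshold in the comparisons shown. A star marks camera passing with the preset and estimated correlations, a dot with the preset alone. Medians are not drawn. For UTX against EV in full medium the squamous median log2 fold change was -2.54 and the YAP and TGF-beta median 0.59.

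In sphere medium UTX was again compared with EV. KDM6A rose (log2 fold change 6.72 ± 0.05, adjusted p = 4.17e-27). The basal keratins KRT5 and KRT14 fell from 12517 ± 539.8 to 3310.4 ± 196 CPM and from 1327 ± 79.9 to 338 ± 9.34 CPM (adjusted p = 9.21e-18 and 9.79e-19). KRT13 fell from 6529 ± 193 to 1650.3 ± 43.4 CPM (log2 fold change -1.98 ± 0.04, adjusted p = 4.13e-20), while UPK1B, a uroplakin of the urothelial surface, rose from 145 ± 4.13 to 384 ± 16.7 CPM (adjusted p = 9.38e-18). ELF3, a transcription factor of luminal cells, rose from 4.57 ± 0.66 to 17.4 ± 0.75 CPM (log2 fold change 1.93 ± 0.08, adjusted p = 2.25e-14). The matrix gene SPARC fell from 28.7 ± 1.21 to 0.38 ± 0.06 CPM, a 75.6-fold change (adjusted p = 9.79e-19). Among the other largest falls, MEOX1 was at 0.26 ± 0.19 against 9.88 ± 2.8 CPM and the peptidase MME at 0.67 ± 0.21 against 16.2 ± 1.43 CPM (adjusted p = 5.43e-11 and 2.81e-16). TENM2 and CCDC3 fell by log2 fold changes of -4.56 and -4.33 (adjusted p = 8.05e-18 and 2.14e-14). Among the largest rises, TGM3, a transglutaminase of the cornified envelope, went from 1.23 ± 0.22 to 35.9 ± 2.09 CPM (adjusted p = 4.42e-16). GJA5 rose from 0.25 ± 0.01 to 12.3 ± 1.22 CPM, CORO2B from 0.59 ± 0.12 to 20.6 ± 1.71 and CDSN from 0.27 ± 0.09 to 7.56 ± 1.96 (adjusted p = 1.89e-17, 1.02e-18 and 1.95e-10).

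Of the luminal genes in sphere medium, 18 of 31 were higher and 9 lower (18 and 10 adjusted over the list alone), median 0.45 (camera adjusted p = 0.00597, adjusted p = 0.305 with an estimated correlation). Of the basal genes, 9 of 22 were higher and 11 lower (10 and 11 adjusted over the list alone, camera adjusted p = 0.327), among them PKP1, which fell from 525 ± 17.1 to 212 ± 1.92 CPM (adjusted p = 2.16e-15). Squamous genes were mostly higher: 14 of 20 were higher and 4 lower (14 and 4 adjusted over the list alone), median 0.97 (camera adjusted p = 8.72e-05, adjusted p = 0.189 with an estimated correlation). SBSN rose from 38.6 ± 2.27 to 133 ± 5.7 CPM and SPRR3 from 206 ± 9.79 to 548 ± 31.7 CPM (adjusted p = 8.97e-16 and 1.49e-14). Among FGFR and MAPK genes, 13 of 26 were higher and 6 lower (14 and 6 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.152 with an estimated correlation). CCND1 was at 459 ± 13.7 against 175 ± 15.3 CPM and KCNN4 at 98.9 ± 5.87 against 28.8 ± 2.62 CPM. Of the junction genes, 15 of 23 were higher and 4 lower (15 and 4 adjusted over the list alone, camera adjusted p = 0.00406, adjusted p = 0.23 with an estimated correlation). CLDN4 rose from 179 ± 6.87 to 317 ± 6.76 CPM and DSG2 from 332 ± 13.2 to 652 ± 33.9, while DSP fell (log2 fold change -0.60, adjusted p = 1.78e-12). Of the NF-kB targets and cytokines, 11 of 16 were higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.00439, adjusted p = 0.189 with an estimated correlation). The cytokine IL1B rose from 55.7 ± 4.2 to 117 ± 3.92 CPM, while SOD2 fell (log2 fold change -0.55, adjusted p = 2.07e-11).

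Of the YAP and TGF-beta targets in sphere medium, 12 of 20 were higher and 4 lower (12 and 4 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.32 with an estimated correlation). Cholesterol synthesis genes were lower: 1 of 24 was higher and 16 lower (1 and 16 adjusted over the list alone, camera adjusted p = 2.07e-06, adjusted p = 0.189 with an estimated correlation). INSIG1 and LSS had log2 fold changes of -0.81 and -0.82 (adjusted p = 5.54e-14 and 2.65e-12). Of the stress response genes, 2 of 20 were higher and 13 lower (2 and 13 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.345 with an estimated correlation). The serine synthesis gene PHGDH fell from 344 ± 21.9 to 82.7 ± 7.06 CPM and ASNS, the asparagine synthetase, from 273 ± 23.1 to 106 ± 13.7 CPM. Every ribosomal protein gene was lower: 0 of 30 were higher and 30 lower (0 and 30 adjusted over the list alone), median -0.50 (camera adjusted p = 2.16e-17, adjusted p = 0.23 with an estimated correlation). By edgeR, 4477 genes were higher and 5027 lower, 1195 and 523 of them by at least 2-fold, and 10710 genes (54.6%) were separated. Of 19612 genes compared, 2700 were higher with UTX in both media (1272.1 expected) and 3311 lower in both (1468.1 expected). Pearson r was 0.433 across genes, which are not independent replicates (permutation p = 1e-05, the smallest possible).

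The next comparison asked whether the demethylase site was needed: HEAA replaces 2 residues that bind the iron of the catalytic domain. In full medium HEAA against EV raised KDM6A (log2 fold change 5.31 ± 0.05, adjusted p = 6.51e-26). KRT1 fell to 0.42 ± 0.33 CPM from 46.8 ± 2.56 and S100A8 to 0.34 ± 0.13 CPM from 20.5 ± 2.28 (adjusted p = 1.14e-17 and 1.09e-17), and DSG1 had 3 counts against 517, a ratio of 146 (95% counting interval 49.8 to 711). The membrane linker MSN rose from 2.75 ± 0.33 to 36.1 ± 0.93 CPM and the neuronal adhesion gene SLITRK6 from 0.96 ± 0.19 to 14.0 ± 0.53 CPM (adjusted p = 1.17e-20 and 1.32e-12). Of the squamous genes, 1 of 20 was higher and 10 lower (1 and 10 adjusted over the list alone, camera adjusted p = 0.00828, adjusted p = 0.318 with an estimated correlation). Of the replication genes, 0 of 20 were higher and 20 lower (0 and 20 adjusted over the list alone, camera adjusted p = 3.25e-14, adjusted p = 0.192 with an estimated correlation). Of the YAP and TGF-beta targets, 16 of 20 were higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 1.31e-07, adjusted p = 0.192 with an estimated correlation). Among ribosomal protein genes, 0 of 30 were higher and 30 lower (0 and 30 adjusted over the list alone, camera adjusted p = 1.76e-20, adjusted p = 0.199 with an estimated correlation). By edgeR, 4554 genes were higher and 4975 lower. Of these calls, 3975 were higher with both proteins (1295.2 expected) and 4554 lower with both (1452.3 expected). The 2 effects shared EV libraries, with r = 0.841 and covariance 0.454 (0.027 from sharing alone).

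In sphere medium HEAA against EV raised KDM6A (log2 fold change 6.85 ± 0.05, adjusted p = 2.98e-27) and TGM3, which went from 1.23 ± 0.22 to 36.9 ± 2.59 CPM (adjusted p = 6.05e-16). The cornification gene CDSN rose from 0.27 ± 0.09 to 8.22 ± 0.35 CPM, and SPARC fell from 28.7 ± 1.21 to 1.07 ± 0.22 CPM (adjusted p = 1.63e-10 and 1.74e-18). MEOX1 also fell (log2 fold change -3.93, adjusted p = 3.9e-10), as did POLR2J2 (log2 fold change -4.82, adjusted p = 0.00116), whose near-identical copies make its identity uncertain. Squamous genes were mostly higher with HEAA: 16 of 20 were higher and 1 lower (16 and 1 adjusted over the list alone). In the FGFR and MAPK list 14 of 26 were higher and 3 lower (14 and 5 adjusted over the list alone). These lists passed both ways (camera adjusted p = 6.32e-13 and 0.00013; adjusted p = 0.0189 and 0.0189 with an estimated correlation). Of the ribosomal protein genes, 0 of 30 were higher and 30 lower (0 and 30 adjusted over the list alone, camera adjusted p = 8.05e-19, adjusted p = 0.206 with an estimated correlation). By edgeR, 3906 genes were higher and 4212 lower. In sphere medium 3234 genes were higher with both proteins (890.4 expected) and 3452 lower (1077.2 expected), with r = 0.802 and 0.477 from shared controls alone.

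Wild type UTX was then compared with HEAA directly. In full medium KDM6A was lower in UTX than in HEAA (log2 fold change -0.26 ± 0.04, adjusted p = 2.65e-05), so the 2 groups did not carry equal amounts of transgene RNA. MME was at 0.81 ± 0.23 against 4.77 ± 0.45 CPM and SPARC at 1.13 ± 0.31 against 4.2 ± 0.56 CPM, both lower with UTX (adjusted p = 3.44e-10 and 1.31e-08). CD22 was lower too (log2 fold change -1.86, adjusted p = 1.32e-05), while the monooxygenase MOXD1 was higher with UTX, at 4.32 ± 0.28 against 1.62 ± 0.29 CPM (adjusted p = 3.86e-05), as was the zinc finger gene ZNF350 (log2 fold change 1.26, adjusted p = 0.00195). KRT5 was at 167 ± 9.37 CPM with UTX and 479 ± 29 with HEAA, and MCM3 at 84 ± 0.95 and 111 ± 1.16. Replication genes were lower with UTX than with HEAA: 0 of 20 were higher and 18 lower (0 and 19 adjusted over the list alone), median -0.43 (camera adjusted p = 6.06e-21, adjusted p = 0.061 with an estimated correlation). By edgeR, 1756 genes were higher and 2442 lower, 47 and 136 of them by at least 2-fold.

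In sphere medium KDM6A was again lower in UTX than in HEAA (log2 fold change -0.13 ± 0.04, adjusted p = 0.0139). The mucin MUC16 was higher with UTX, at 61.8 ± 2.65 against 21.9 ± 1.77 CPM, and GJA5 too, at 12.3 ± 1.22 against 4.79 ± 0.51 CPM (adjusted p = 1.48e-08 and 3.21e-10). CPE, FHL1 and CACNA1H were lower with UTX, with log2 fold changes of -1.68, -1.65 and -1.61 (adjusted p = 3.13e-08, 6.9e-09 and 2.1e-05). Among squamous genes, 0 of 20 were higher and 12 lower (0 and 13 adjusted over the list alone), median -0.31, a call that passed both ways (camera adjusted p = 2.06e-10, adjusted p = 0.0473 with an estimated correlation). Nearly all mitosis genes were lower with UTX: 0 of 20 were higher and 19 lower (0 and 20 adjusted over the list alone, camera adjusted p = 2.57e-12, adjusted p = 0.372 with an estimated correlation). Replication genes were lower as well: 0 of 20 were higher and 11 lower (0 and 13 adjusted over the list alone, camera adjusted p = 1.11e-07, adjusted p = 0.372 with an estimated correlation). By edgeR, 1742 genes were higher and 2189 lower, 87 and 102 of them by at least 2-fold.

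The medium itself was compared in EV cells, sphere against full. KDM6A fell (log2 fold change -1.09 ± 0.06, adjusted p = 1.03e-13). The basal keratin KRT14 rose from 12.7 ± 0.28 to 1327 ± 79.9 CPM and the desmosomal gene PKP1 from 11.3 ± 0.84 to 525 ± 17.1 CPM (adjusted p = 1.41e-26 and 9.06e-25). KRT16, a keratin of activated skin, rose from 0.87 ± 0.08 to 586 ± 5 CPM and the cornified envelope gene SPRR1B from 0.92 ± 0.2 to 398 ± 31.2 CPM (adjusted p = 5.11e-25 and 4.14e-24). The lipoxygenase ALOX15B had 1834 counts against 0, at least 700-fold higher (adjusted p = 1.84e-16), and SPRR1A 548 against 0, at least 209-fold higher (adjusted p = 1.19e-13). The protease KLK12 had 2537 counts against 2, a ratio of 1450 (95% counting interval 402 to 12000). ATOH8 had 2 counts in sphere and 5526 in full medium, a ratio of 2410 (667 to 19900), and the growth factor TGFB2 1 and 3057, a ratio of 2670 (478 to 105000). The YAP target ANKRD1 had 1 and 2449 counts, a ratio of 2140 (383 to 84500). PSG5 fell from 75.1 ± 4.76 to 0.09 ± 0.02 CPM and THSD7A from 54.1 ± 2.12 to 0.07 ± 0.06 CPM (adjusted p = 2.25e-24 and 4.09e-22).

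Basal, squamous, FGFR and MAPK, and cholesterol synthesis genes rose in sphere medium and passed both ways. Among basal genes, 18 of 22 were higher and 4 lower (18 and 4 adjusted over the list alone, camera adjusted p = 1.19e-07, adjusted p = 0.0437 with an estimated correlation). Among squamous genes, 19 of 20 were higher and 1 lower (19 and 1 adjusted over the list alone), median 5.20 also with counts of 0 set to the floor (camera adjusted p = 4.79e-09, adjusted p = 0.0401 with an estimated correlation). Among FGFR and MAPK genes, 18 of 26 were higher and 6 lower (18 and 6 adjusted over the list alone, camera adjusted p = 0.00161, adjusted p = 0.0437 with an estimated correlation). The feedback phosphatase DUSP6 went up from 23.9 ± 1.55 to 463 ± 9.42 CPM, SPRY4 from 3.08 ± 0.23 to 60.5 ± 1.48 and ETV4 from 13.3 ± 0.19 to 92.7 ± 2.8 (adjusted p = 1.39e-24, 3.73e-23 and 3.49e-21). Of the cholesterol synthesis genes, 24 of 24 were higher and 0 lower (24 and 0 adjusted over the list alone, camera adjusted p = 1.35e-15, adjusted p = 0.0401 with an estimated correlation). INSIG1 was at 214 ± 7.77 against 43.5 ± 0.8 CPM. SCD rose 7.85-fold (adjusted p = 9.31e-24). Of the hypoxia and glycolysis genes, 19 of 23 were higher and 2 lower (19 and 2 adjusted over the list alone, camera adjusted p = 3.35e-06, adjusted p = 0.191 with an estimated correlation).

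Luminal genes were mostly lower in sphere medium: 10 of 31 were higher and 19 lower (10 and 19 adjusted over the list alone), median -0.80 (camera adjusted p = 0.0113, adjusted p = 0.245 with an estimated correlation). FABP4, a fatty acid binding protein, fell from 343 ± 7.85 to 7.76 ± 0.45 CPM, KRT7 from 84.4 ± 2.76 to 1.77 ± 0.3 and ELF3 from 104 ± 2.82 to 4.57 ± 0.66 (adjusted p = 6.34e-24, 8.33e-24 and 3.68e-23). Of the YAP and TGF-beta targets, 3 of 20 were higher and 16 lower (3 and 16 adjusted over the list alone, camera adjusted p = 4.75e-08, adjusted p = 0.0655 with an estimated correlation). THBS1 fell from 2272 ± 92.6 to 10.7 ± 2.15 CPM. Of the replication genes, 2 of 20 were higher and 18 lower (2 and 18 adjusted over the list alone, camera adjusted p = 8.22e-07, adjusted p = 0.191 with an estimated correlation). Mitochondrial RNA fell: 0 of 13 were higher and 13 lower (0 and 13 adjusted over the list alone, camera adjusted p = 5.34e-05, adjusted p = 0.305 with an estimated correlation). Ribosomal protein genes rose: 29 of 30 were higher and 0 lower (29 and 1 adjusted over the list alone, camera adjusted p = 1.02e-05, adjusted p = 0.408 with an estimated correlation). By edgeR, 6503 genes were higher and 6355 lower, 1609 and 2555 of them by at least 2-fold, and 13651 genes (69.5%) were separated. Against the UTX effect in full medium, 2328 genes were higher with UTX and lower in sphere medium (1807.5 expected) and 2876 the reverse (1898.9 expected). Another 1637 were higher in both (1848.2 expected) and 1624 lower (1857.1 expected). Here r was -0.105 and covariance -0.108 (0.027 from shared EV_full alone).

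**Figure D3:**
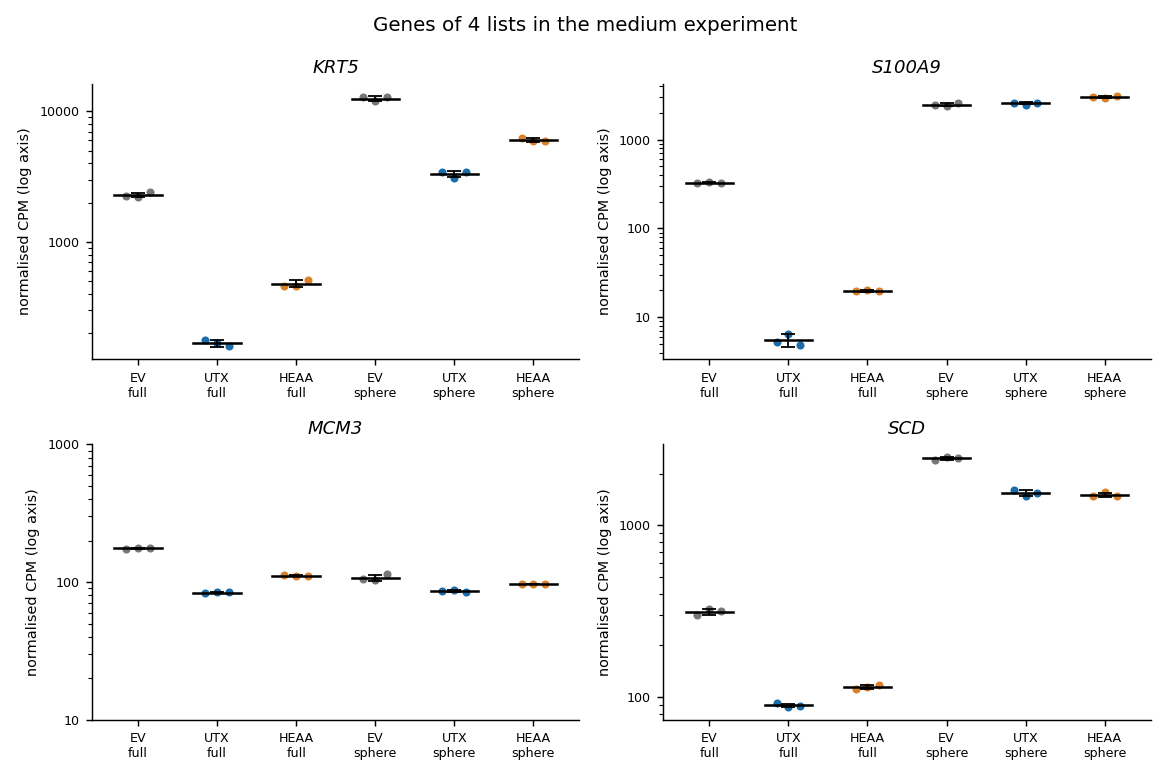
KRT5, S100A9, MCM3 and SCD in CPM on log axes in the 6 groups of the first experiment, with 1 point per library and the mean ± SD of 3 libraries. KRT5 was at 2287 ± 96.5 CPM in EV and 167 ± 9.37 in UTX in full medium.

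The same change of medium was tested in UTX cells. KDM6A rose, where in EV it had fallen (log2 fold change 0.57 ± 0.04, adjusted p = 7.43e-12). PI3 had 29543 counts in sphere and 2 in full medium, a ratio of 18800 (95% counting interval 5200 to 155000). SERPINB3 had 4506 against 0 counts, at least 1910-fold higher, and DSG1 2863 against 0, at least 1210-fold higher. ATOH8 fell from 64.4 ± 2.93 to 0.06 ± 0.02 CPM, PSG5 from 119 ± 2 to 0.2 ± 0.05 and the lysyl oxidase LOXL4 from 206 ± 5.77 to 0.49 ± 0.04 (adjusted p = 2.15e-23, 5.01e-25 and 7.34e-24). FGFR and MAPK genes were mostly higher: 21 of 26 were higher and 2 lower (21 and 2 adjusted over the list alone). YAP and TGF-beta targets were lower: 0 of 20 were higher and 18 lower (0 and 18 adjusted over the list alone). These lists passed both ways (camera adjusted p = 2.44e-07 and 2.35e-12; adjusted p = 0.00534 and 0.0204 with an estimated correlation). By edgeR, 6891 genes were higher and 6945 lower.

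In HEAA cells KDM6A also rose in sphere medium (log2 fold change 0.44 ± 0.04, adjusted p = 5.18e-10). TGM3 had 3455 counts against 0, at least 1080-fold higher, SPRR2E 1969 against 0, at least 616-fold higher, and SPRR2D 12951 against 2, a ratio of 6070 (95% counting interval 1680 to 50200). ATOH8 fell from 64.7 ± 0.89 to 0.07 ± 0.03 CPM, LOXL4 from 211 ± 9.43 to 0.37 ± 0.15 and PSG5 from 120.2 ± 3.65 to 0.25 ± 0.07. By edgeR, 6754 genes were higher and 7135 lower.

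Whether the effect of UTX differed between the media was tested as an interaction. The KDM6A effect was larger in sphere medium (difference 1.67 in log2, adjusted p = 4.26e-14). S100A7, a skin antimicrobial protein, had 0 counts in UTX against 66 in EV in full medium, at least 19.6-fold lower, and rose in sphere medium (log2 fold change 2.93, adjusted p = 1.47e-09). The difference was 10.19 ± 0.94 (adjusted p = 1.4e-07). The differences were 9.59 for SERPINB3 and 8.56 for PI3 (adjusted p = 4.23e-11 and 2.25e-13), and such values depend on the prior count where a group had no counts. The stress gene SESN3 rose with UTX in full medium (log2 fold change 3.79) and fell in sphere medium (-1.35), a difference of -5.14 (adjusted p = 4.1e-11). TCIM differed by -3.76 and the exchanger gene SLC24A3 by -3.66 (adjusted p = 2.75e-11 and 4.89e-08). Replication genes fell less in sphere medium: for the difference, 20 of 20 were higher and 0 lower (20 and 0 adjusted over the list alone), with a median difference of 0.72. In the same direction, 18 of 26 were higher and 1 lower (18 and 1 adjusted over the list alone) in the FGFR and MAPK list, and 16 of 20 were higher and 0 lower (17 and 0 adjusted over the list alone) in the squamous list. These 3 lists passed both ways (camera adjusted p = 6.52e-18, 1.02e-09 and 5.33e-09; adjusted p = 0.0344, 0.00191 and 0.0339 with an estimated correlation). By edgeR, 4143 genes were higher and 3176 lower.

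For HEAA the same test gave a KDM6A difference of 1.54 (adjusted p = 4.87e-13). S100A7 differed by 10.45 and S100A8 by 6.44 (adjusted p = 1.65e-07 and 9.29e-17). CYP4F22, a skin lipid hydroxylase, differed by 6.37, SESN3 by -4.37 and LOXL2 by -3.47 (adjusted p = 4.62e-06, 1.53e-09 and 0.00347). In the squamous list 15 of 20 were higher and 0 lower (15 and 0 adjusted over the list alone). In the FGFR and MAPK list 18 of 26 were higher and 2 lower (18 and 3 adjusted over the list alone), and in the replication list 20 of 20 were higher and 0 lower (20 and 0 adjusted over the list alone). The 3 lists passed both ways (camera adjusted p = 3.57e-11, 8.06e-09 and 5.7e-16; adjusted p = 0.0185, 0.00154 and 0.0495 with an estimated correlation). By edgeR, 3678 genes were higher and 2803 lower.

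The second experiment asked how UTX acted beside FGFR3. FGFR3 (ENSG00000068078, chromosome 4, 1793293 to 1808872 on GRCh38) was at 1301 ± 74.9 CPM in EV and 1243 ± 47.4 in UTX with the wild type vector, and at 2322 ± 109.5 and 2588 ± 44.2 with S249C. With wild type FGFR3, UTX raised KDM6A (log2 fold change 5.70 ± 0.13, adjusted p = 5.82e-13), and FGFR3 itself did not pass (log2 fold change -0.07 ± 0.05, adjusted p = 0.461). The retinal transporter gene ABCA4 fell from 16.1 ± 1.47 to 0.24 ± 0.09 CPM (log2 fold change -6.03 ± 0.18, adjusted p = 1.02e-11), and PI3 from 13.6 ± 0.37 to 1.04 ± 0.36 CPM (log2 fold change -3.69 ± 0.23, adjusted p = 5.2e-08). KRT5 fell from 1933 ± 75.1 to 1168 ± 27.1 CPM, KRT1 from 9.68 ± 1.52 to 1.13 ± 0.32 and S100A9 from 70.4 ± 2.2 to 23.4 ± 0.44 (adjusted p = 1.65e-08, 1.42e-06 and 3.25e-07). IGFBP2, which binds insulin-like growth factors, rose from 5.47 ± 0.49 to 63.8 ± 3.78 CPM, TMEM265 from 0.23 ± 0.23 to 5.38 ± 0.75 and TLL2 from 1.62 ± 0.3 to 8.84 ± 0.55 (adjusted p = 2.22e-11, 9.69e-06 and 2.51e-08). ST6GALNAC2 rose too (log2 fold change 2.42, adjusted p = 4.09e-07), and ALPG and CYP1A2 fell (log2 fold change -2.81, adjusted p = 1.05e-05; log2 fold change -2.61, adjusted p = 5.73e-06).

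Junction genes rose with UTX beside wild type FGFR3: 14 of 23 were higher and 0 lower (17 and 0 adjusted over the list alone), median 0.24, passing both ways (camera adjusted p = 2.91e-10, adjusted p = 0.0251 with an estimated correlation). The tight junction genes CLDN1 and CGN rose from 137 ± 6.01 to 204 ± 6.06 CPM and from 24.8 ± 0.53 to 39.5 ± 0.78 CPM (adjusted p = 1.06e-06 and 2.12e-06). Replication genes fell: 0 of 20 were higher and 16 lower (0 and 17 adjusted over the list alone, camera adjusted p = 1.56e-10, adjusted p = 0.0482 with an estimated correlation). Of the NF-kB and cytokine gene IDs (17 for 16 genes here, as SOD2 had 2), 9 of 17 were higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.00103, adjusted p = 0.0444 with an estimated correlation). Of the basal genes, 9 of 21 were higher and 2 lower (10 and 5 adjusted over the list alone, camera adjusted p = 0.00607, adjusted p = 0.258 with an estimated correlation). PKP1 went up from 14.2 ± 1.43 to 48.0 ± 2 CPM and the cadherin CDH3 from 317 ± 8.11 to 428 ± 3.05. Of the squamous genes, 1 of 10 was higher and 4 lower (2 and 5 adjusted over the list alone, camera adjusted p = 0.00607, adjusted p = 0.253 with an estimated correlation). Of the luminal genes, 7 of 29 were higher and 10 lower (10 and 11 adjusted over the list alone, camera adjusted p = 0.56). UPK2 rose from 13.5 ± 0.57 to 22.4 ± 0.81 CPM (adjusted p = 1.37e-05). Of the FGFR and MAPK genes, 6 of 26 were higher and 7 lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.506).

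By edgeR, 1758 genes were higher and 1166 lower, 211 and 200 of them by at least 2-fold. The UTX effects in the 2 experiments, which shared no library, correlated across 17228 genes. There r was 0.258 and rho 0.343 (permutation p = 1e-05, the smallest possible). Higher in both were 1229 genes (527.2 expected) and lower in both 743 (350.6 expected); genes are not independent replicates, and this was 1 of 8 relations computed.

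Beside S249C, UTX raised KDM6A (log2 fold change 6.21 ± 0.13, adjusted p = 4.55e-13). FGFR3 was at 2588 ± 44.2 against 2322 ± 109.5 CPM (log2 fold change 0.16, adjusted p = 0.0403), which did not hold without EV_FGFR3S249C replicate 1 or 2 (log2 fold change 0.12 and 0.17) or UTX_FGFR3S249C replicate 1 or 2 (0.15 and 0.15). Nor did it hold with the replicate number as a block or with only the groups compared (0.16 and 0.16). IGFBP2 rose from 2.34 ± 0.42 to 52.2 ± 7.21 CPM, TMEM265 from 0.08 ± 0.13 to 7.85 ± 2.26 and ANKRD22 from 1.91 ± 0.14 to 11.3 ± 0.34 (adjusted p = 6.52e-12, 6.35e-07 and 4.49e-10). RGPD6, a member of a family of near-identical copies and so of uncertain identity, was higher as well (log2 fold change 5.78, adjusted p = 0.00718). The teneurin TENM3 fell from 7.08 ± 0.53 to 0.7 ± 0.18 CPM, PI3 from 4.03 ± 0.9 to 0.47 ± 0.25 and ZNF618 from 6.7 ± 0.39 to 1.77 ± 0.27 (adjusted p = 1.7e-08, 2e-06 and 1.25e-07). S100A8 and LNCOC1 fell (log2 fold change -2.07, adjusted p = 2.22e-06; log2 fold change -1.87, adjusted p = 0.000193), and KRT5 fell from 1101 ± 11.9 to 758 ± 5.18 CPM (log2 fold change -0.54, adjusted p = 2.59e-07).

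Luminal genes were mostly higher with UTX beside S249C: 15 of 29 were higher and 4 lower (16 and 5 adjusted over the list alone), median 0.16 (camera adjusted p = 9.98e-05, adjusted p = 0.235 with an estimated correlation). UPK2 rose from 10.2 ± 1 to 20.5 ± 1.82 CPM, ELF3 from 14.2 ± 1.3 to 24.5 ± 0.93 and CYP2J2 by a log2 fold change of 0.76 (adjusted p = 5.12e-07, 9.96e-07 and 1.75e-06). Junction genes passed both ways: 16 of 23 were higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 8.85e-13, adjusted p = 0.0115 with an estimated correlation). CGN was at 47.9 ± 3.14 against 22.2 ± 1.53 CPM and the plakoglobin gene JUP at 718 ± 23.1 against 429 ± 19.2 CPM. Among basal genes, 12 of 21 were higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 6.53e-05, adjusted p = 0.17 with an estimated correlation). Of the replication genes, 0 of 20 were higher and 9 lower (0 and 10 adjusted over the list alone, camera adjusted p = 9.98e-05, adjusted p = 0.235 with an estimated correlation). Of the NF-kB and cytokine gene IDs, with SOD2 again entered by 2, 8 of 17 were higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.00474, adjusted p = 0.0813 with an estimated correlation). Camera called the list higher, as its median of 0.25 was, while its mean was -0.17. Among FGFR and MAPK genes, 7 of 26 were higher and 6 lower (8 and 7 adjusted over the list alone, camera adjusted p = 0.64). Among squamous genes, 2 of 10 were higher and 4 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.796).

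Mitochondrial RNA was higher with UTX beside S249C: 12 of 13 were higher and 0 lower (12 and 0 adjusted over the list alone), median 0.86 (camera adjusted p = 1.96e-07, adjusted p = 0.347 with an estimated correlation). ND6 was at 775 ± 33.5 against 355 ± 138 CPM (adjusted p = 0.000525). Mitochondrial RNA made up 1.93% ± 0.537 of counts in EV_FGFR3S249C, where replicate 1 had 1.32% and the highest replicate 2.34%, against 3.06% ± 0.175 in UTX_FGFR3S249C. By edgeR, 2499 genes were higher and 1672 lower, 279 and 172 of them by at least 2-fold. Beside wild type and S249C FGFR3, 1370 genes were higher with UTX in both (226.5 expected) and 611 lower in both (100.5 expected), with r = 0.255 across genes (permutation p = 1e-05, the smallest possible here).

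S249C was compared with wild type FGFR3 in EV cells, which lack functional UTX. FGFR3 RNA was higher with S249C (log2 fold change 0.84 ± 0.05, adjusted p = 2.37e-07), so the 2 vectors differed in amount as well as in sequence. KDM6A was at 11.6 ± 1.36 against 15.8 ± 1.02 CPM (log2 fold change -0.45, adjusted p = 0.0565) and did not pass. KRT5 fell from 1933 ± 75.1 to 1101 ± 11.9 CPM and DSC3 from 63.0 ± 0.89 to 26.2 ± 2.18 CPM (adjusted p = 4.74e-08 and 6.21e-08). ABCA4 fell from 16.1 ± 1.47 to 0.28 ± 0.05 CPM, the calmodulin-like gene CALML3 from 5.59 ± 0.31 to 1.07 ± 0.22 and the cytoskeletal gene MAP2 from 6.98 ± 0.86 to 1.76 ± 0.26 (adjusted p = 3.54e-11, 1.61e-06 and 3.34e-06). CYP1A2 and EYA2 fell too (log2 fold change -2.68, adjusted p = 1.31e-05; log2 fold change -2.35, adjusted p = 1.14e-06). TENM3 rose from 1.12 ± 0.2 to 7.08 ± 0.53 CPM, the pentraxin PTX3 from 8.51 ± 0.73 to 21.7 ± 0.59 and the anthrax toxin receptor ANTXR2 from 12.1 ± 1.07 to 29.4 ± 1.97 (adjusted p = 7.47e-07, 4.78e-07 and 7.99e-08). The trefoil factor TFF1 and SUSD2 rose as well (log2 fold change 1.48, adjusted p = 0.00012; log2 fold change 1.32, adjusted p = 6.4e-05).

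Of the feedback and target genes of FGFR and MAPK signalling with S249C, 9 of 26 were higher and 1 lower (13 and 3 adjusted over the list alone), median 0.19 (camera adjusted p = 6.97e-05, adjusted p = 0.0605 with an estimated correlation). DUSP4 rose from 51.4 ± 0.87 to 93.9 ± 3.77 CPM, the inhibitor SPRY4 from 12.03 ± 1.04 to 20.7 ± 0.55 and the ligand EREG by a log2 fold change of 0.46 (adjusted p = 4.74e-08, 1.05e-05 and 4.52e-05). Squamous genes fell: 0 of 10 were higher and 7 lower (0 and 7 adjusted over the list alone), median -0.84, passing both ways (camera adjusted p = 2.73e-07, adjusted p = 0.0361 with an estimated correlation). S100A9 was at 39.1 ± 8.89 against 70.4 ± 2.2 CPM. Of the basal genes with S249C, 1 of 21 was higher and 10 lower (2 and 11 adjusted over the list alone, camera adjusted p = 1.37e-06, adjusted p = 0.0605 with an estimated correlation). Among luminal genes, 2 of 29 were higher and 9 lower (3 and 11 adjusted over the list alone, camera adjusted p = 0.00142, adjusted p = 0.293 with an estimated correlation). KRT13 was at 669.7 ± 15.02 against 997 ± 40.4 CPM. KLF5 and ERBB3 were lower (log2 fold change -0.38, adjusted p = 0.000143; log2 fold change -0.38, adjusted p = 0.000412). Of the mesenchymal genes, 0 of 15 were higher and 7 lower (0 and 8 adjusted over the list alone, camera adjusted p = 4.39e-05, adjusted p = 0.0605 with an estimated correlation). The NF-kB and cytokine list (SOD2 by 2 gene IDs) passed both ways: 5 of 17 were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 0.000217, adjusted p = 0.0361 with an estimated correlation). LIF was higher (log2 fold change 0.54, adjusted p = 0.000481), and the chemokine CXCL5 had 41 counts against 0, at least 13.1-fold higher (adjusted p = 0.00362). The cholesterol synthesis list passed both ways: 0 of 24 were higher and 11 lower (1 and 12 adjusted over the list alone, camera adjusted p = 3.21e-05, adjusted p = 0.0361 with an estimated correlation).

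Of mitochondrial RNA with S249C in EV, 0 of 13 were higher and 5 lower (0 and 10 adjusted over the list alone, camera adjusted p = 2.16e-06, adjusted p = 0.364 with an estimated correlation), at 1.93% of counts against 2.57% with wild type FGFR3. ND6 was at 355 ± 138 against 609 ± 43.2 CPM (adjusted p = 0.0152), which did not hold without EV_FGFR3WT replicate 2 (log2 fold change -0.72). By edgeR, 836 genes were higher and 1252 lower, 92 and 125 of them by at least 2-fold. The 2088 calls fell to 1374 without EV_FGFR3S249C replicate 1, 1255 without EV_FGFR3WT replicate 2 and 1124 without EV_FGFR3WT replicate 3.

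The series title places UTX loss and FGFR3 activation on the same programs, so the UTX effect in full medium was set beside the S249C effect in EV across 17228 genes. Genes higher with UTX and lower with S249C numbered 611 (370.5 expected) and the reverse 385 (246.3 expected). Higher in both were 179 genes (236.4 expected) and lower in both 345 (386.2 expected). The correlation across genes, not independent replicates, was small: r -0.039 (permutation p = 2e-05) and rho -0.098 (permutation p = 1e-05, the smallest possible). Without EV_FGFR3WT replicate 2 r was -0.015 and no longer passed. KRT5, DSC3, S100A9 and KRT13 fell with UTX and with S249C alike, while DUSP4 was at 8.02 ± 0.415 CPM in EV_full and 19.8 ± 1.03 in UTX_full. Within the second experiment, 300 genes were higher with UTX and lower with S249C (113.5 expected), 87 the reverse (50.2 expected), 137 higher with both (75.8 expected) and 217 lower with both (75.3 expected). Both effects shared EV_FGFR3WT: r = 0.446, covariance 0.13 (0.494 and 0.03 from sharing alone).

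**Figure D4:**
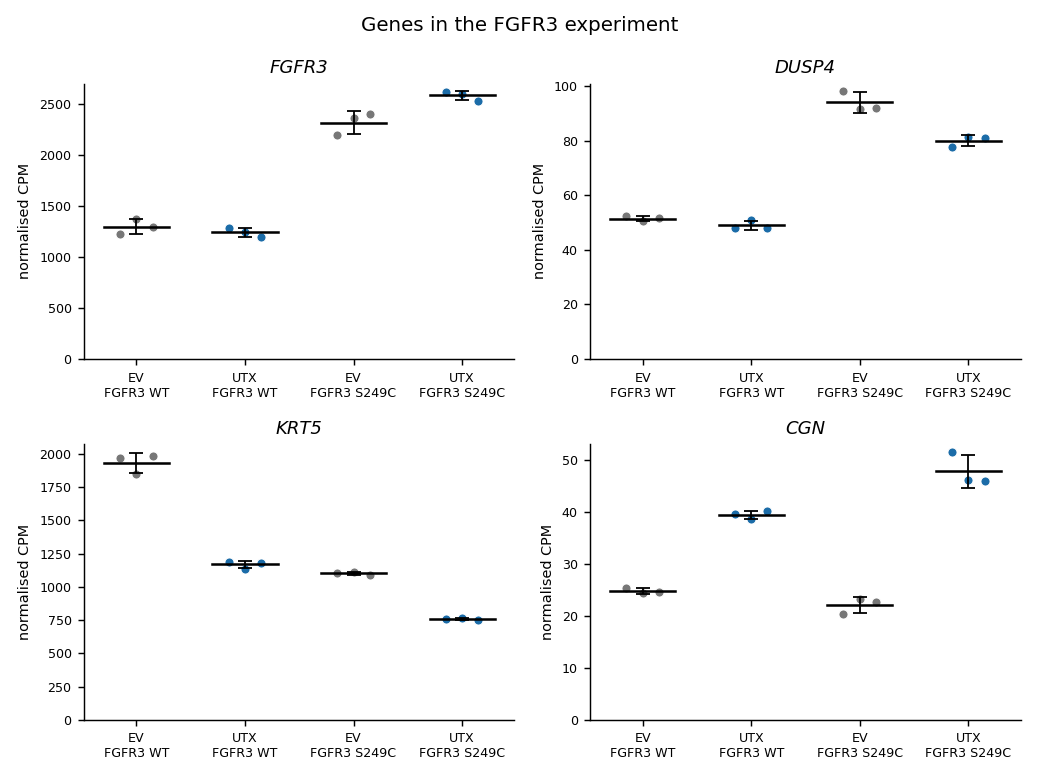
FGFR3, DUSP4, KRT5 and CGN in CPM on linear axes in the 4 groups of the second experiment, with 1 point per library and the mean ± SD of 3 libraries. DUSP4 was at 51.4 ± 0.87 CPM in EV_FGFR3WT, 49.0 ± 1.68 in UTX_FGFR3WT, 93.9 ± 3.77 in EV_FGFR3S249C and 79.95 ± 1.97 in UTX_FGFR3S249C.

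In UTX cells S249C against wild type FGFR3 raised FGFR3 (log2 fold change 1.06 ± 0.05, adjusted p = 6.39e-08), and KDM6A was at 862 ± 141 against 824 ± 73.2 CPM (log2 fold change 0.07, adjusted p = 0.847). ANTXR2 rose from 8.64 ± 0.37 to 23.4 ± 0.71 CPM, the protease ADAMTS12 from 4.13 ± 0.45 to 10.5 ± 1.72 and the adhesion gene CEACAM6 from 1.57 ± 0.08 to 3.9 ± 0.33 (adjusted p = 1.08e-07, 2.3e-05 and 0.000122). The collagen COL4A4 fell from 14.6 ± 1.46 to 5.32 ± 0.37 CPM, and SERPINB13 and MFAP3L fell (log2 fold change -1.24, adjusted p = 0.000122; log2 fold change -1.12, adjusted p = 0.000256). In the FGFR and MAPK list 8 of 26 were higher and 0 lower (10 and 1 adjusted over the list alone, camera adjusted p = 2.47e-09, adjusted p = 0.0187 with an estimated correlation). In the NF-kB and cytokine list (SOD2 by 2 gene IDs) 3 of 17 were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 6.17e-05, adjusted p = 0.0187 with an estimated correlation). Both lists passed both ways. Among luminal genes, 5 of 29 were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.000309, adjusted p = 0.244 with an estimated correlation). By edgeR, 332 genes were higher and 259 lower, 37 and 18 of them by at least 2-fold. The 591 calls fell to 379 without UTX_FGFR3S249C replicate 2, and to 307, 291 and 353 without UTX_FGFR3WT replicates 1, 2 and 3.

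Whether UTX acted differently beside the 2 FGFR3 forms was tested as an interaction, which is the same test as a different S249C effect with UTX. KDM6A did not pass (difference 0.51, adjusted p = 0.278), but did without UTX_FGFR3S249C replicate 3 (0.64), and FGFR3 did not pass (0.22, adjusted p = 0.257). ABCA4 fell with UTX beside wild type FGFR3 but did not pass beside S249C (log2 fold changes -6.03 and -1.06), a difference of 4.97 (adjusted p = 0.000465). CALML3 differed by 2.97 and MAP2 by 2.37 (adjusted p = 0.000143 and 0.000483). Both, like ABCA4, had fallen with S249C in EV, leaving less room to fall. The dynein gene DNAH1 differed by -2.14, ZNF618 by -1.30 and TUT1 (ENSG00000255508) by -1.09 (adjusted p = 0.00088, 0.00523 and 0.00922). Of the luminal genes, 7 of 29 were higher and 0 lower (11 and 0 adjusted over the list alone), median 0.25 (camera adjusted p = 1.12e-11, adjusted p = 0.0934 with an estimated correlation). Of the squamous genes, 2 of 10 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 3.88e-05, adjusted p = 0.0934 with an estimated correlation). Among junction genes, 3 of 23 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.000206, adjusted p = 0.0934 with an estimated correlation). Of mitochondrial RNA, 0 of 13 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 6.6e-09, adjusted p = 0.316 with an estimated correlation).

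Among basal genes, 1 of 21 was higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0441, adjusted p = 0.433 with an estimated correlation), with a median of 0.12 and a mean of -0.02. That call was lost without EV_FGFR3WT replicate 2 (adjusted p = 0.153), UTX_FGFR3WT replicate 2 or 3 (0.091 and 0.0776), EV_FGFR3S249C replicate 1 (0.396) or UTX_FGFR3S249C replicate 2 (0.133). By edgeR, 111 genes were higher and 22 lower, 133 in all. That count was 76 and 88 without EV_FGFR3S249C replicates 1 and 3, and 70, 68 and 58 without EV_FGFR3WT replicates 1, 2 and 3. It was 71, 73 and 248 without UTX_FGFR3S249C replicates 1, 2 and 3, and 80, 65 and 66 without UTX_FGFR3WT replicates 1, 2 and 3.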

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

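The tests of pseudogenes, of scaling, of KDM6A RNA and of a single library on mitochondrial RNA were chosen only after the result was seen, while those of length and GC content, of power and of all sample splits were written before. No group had enough samples for a test of samples far from the others, so the 3 interactions stand here because an effect differed between 2 conditions. The splits of samples and the patterns weighed follow.

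The UTX effect differed between full and sphere medium in 7319 genes. The differences in log2 were 1.67 for KDM6A, 10.19 for S100A7, 9.59 for SERPINB3, 8.56 for PI3, -5.14 for SESN3, -3.76 for TCIM and -3.66 for SLC24A3. The lists that differed were squamous (camera adjusted p = 5.33e-09), FGFR and MAPK (1.02e-09), mitosis (0.00887), replication (6.52e-18), NF-kB and cytokines (0.00582), fatty acid synthesis (0.00052) and stress response (2.39e-08). With an estimated correlation mitosis, NF-kB, fatty acid and stress genes did not pass (adjusted p = 0.651, 0.109, 0.109 and 0.102). Of 100 splits of these samples 2 gave as many genes, the real one with 7140 and 1 with 11655 that swaps the labels within 1 medium and so tests the sum of the 2 effects. The highest of the rest was 5783.

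The HEAA effect differed between the media in 6481 genes. The differences were 1.54 for KDM6A, 10.45 for S100A7, 6.44 for S100A8, 6.37 for CYP4F22, -4.37 for SESN3, -4.08 for POLR2J2, whose identity is uncertain, and -3.47 for LOXL2. The lists were squamous (camera adjusted p = 3.57e-11), FGFR and MAPK (8.06e-09), replication (5.7e-16), NF-kB and cytokines (0.0172), fatty acid synthesis (0.00109), hypoxia and glycolysis (0.00248), stress response (4.69e-07) and ribosomal proteins (0.000657). The last 5 did not pass with an estimated correlation (adjusted p = 0.18, 0.173, 0.406, 0.159 and 0.613). Of 100 splits 2 gave as many genes, the real one with 6503 and the label swap with 9978, and the highest of the rest was 4474.

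The UTX effect differed between wild type and S249C FGFR3 in 133 genes, a count that depended on the fit: 80 with the replicate block, 77 at 5 CPM, 58 to 248 with 1 library left out and 260 without EV_FGFR3S249C replicate 1 and UTX_FGFR3S249C replicate 3. The differences were 4.97 for ABCA4, 2.97 for CALML3, 2.37 for MAP2, -2.14 for DNAH1, -1.3 for ZNF618 and -1.09 for TUT1. The lists were luminal (camera adjusted p = 1.12e-11), basal (0.0441), squamous (3.88e-05), mesenchymal (0.0441), junction (0.000206), replication (0.00683), cholesterol synthesis (0.00205), fatty acid synthesis (7.18e-05) and mitochondrial RNA (6.6e-09). None passed with an estimated correlation (adjusted p = 0.0934, 0.433, 0.0934, 0.359, 0.0934, 0.359, 0.0934, 0.227 and 0.316 in the same order). The basal and mesenchymal calls were lost without EV_FGFR3WT replicate 2 (adjusted p = 0.153 and 0.0804), UTX_FGFR3WT replicate 2 (0.091 and 0.0749) or 3 (0.0776 and 0.075), or EV_FGFR3S249C replicate 1 (0.396 and 0.27). The basal call was also lost without UTX_FGFR3S249C replicate 2 (0.133), the mesenchymal one without UTX_FGFR3S249C replicate 1 (0.0739) or EV_FGFR3WT replicate 3 (0.0503), and replication without EV_FGFR3S249C or UTX_FGFR3S249C replicate 3 (0.0592 and 0.0898). Of 100 splits 2 gave as many genes, the real one with 133 and the label swap with 5644, and the highest of the rest was 106.

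The 10 splits of each pair of groups are too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. Splits were fitted on the groups compared alone, with their own filter and dispersion, so real counts here differ from those of the fit to all groups. The real count and the highest of the other splits were 11283 and 0 for UTX against EV in full medium, 8965 and 0 in sphere medium, 10040 and 0 for HEAA in full medium and 7312 and 0 in sphere medium. They were 4066 and 4 for UTX against HEAA in full medium and 3835 and 0 in sphere medium. For sphere against full medium they were 12281 and 0 in EV, 13021 and 0 in UTX and 13354 and 0 in HEAA. For UTX against EV they were 3928 and 0 with wild type FGFR3 and 2929 and 1 with S249C, and for S249C against wild type FGFR3 2200 and 1 in EV and 435 and 2 in UTX.

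Ribosomal protein genes were lower with UTX and with HEAA in both media, which may reflect biology or a loss of short transcripts. Coding genes matched in length and GC content had medians of 45.4%, 23.2%, 35.5% and 8.6% of the ribosomal ones (highest upper bound 55.2%). Whether such a loss caused the fall cannot be told, as matched lengths may not be those expressed. Reads moved to pseudogenes were excluded, since 100.1% or more of the fall was left when 404 pseudogenes were added. Scaling was excluded, since the ribosomal median lay at least 0.42 below that of all genes (nearest value -0.42).

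The UTX effect was smaller beside wild type FGFR3 than in full medium. KDM6A CPM without TMM factors in UTX libraries there was 132.6% of that in full medium, which across kits and vectors cannot exclude less UTX. Lower power was excluded, since the SD of log2 fold changes after removal of their error was 40.2% (38.2% to 42.2%) of that in full medium. The library kit, the vectors and the added FGFR3 differed together between the experiments, so any of them could account for it.

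Camera called mitochondrial RNA lower with S249C in EV and higher with UTX beside S249C, and EV_FGFR3S249C replicate 1, with 1.32% of counts, may drive it. Without that library 54.1% (41.9% to 61.6%) of the S249C median was left, with camera adjusted p = 3.67e-07 and 8 of 13 members past the threshold. For UTX beside S249C 70.6% (63.8% to 72%) was left, with camera adjusted p = 2.41e-12. These ranges over genes cannot exclude spread between libraries, and other causes were not tested. Neither call passed with all libraries and an estimated correlation (adjusted p = 0.364 and 0.347).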

How the results depend on the processing

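The fits without both EV_FGFR3S249C replicate 1 and UTX_FGFR3S249C replicate 3 were chosen only after the result was seen, and all other alternatives before. No result reversed under any alternative. The luminal list lost all its calls with an estimated correlation. In sphere medium these were UTX (adjusted p = 0.305) and HEAA (0.357) against EV and UTX against HEAA (0.468). The others were sphere medium in EV (0.245) and UTX (0.38), UTX beside S249C (0.235), S249C in EV (0.293) and UTX (0.244), and the UTX by FGFR3 interaction (0.0934). The count of genes with a UTX by FGFR3 interaction moved from 133 to 80 with the replicate block. It was 77 with the filter at 5 CPM, which tested fewer genes, and 260 without both libraries named above. The cause of the first and the last was not tested. Block fits changed few other calls, among them FGFR3 with UTX beside S249C, which was lost. Own-number correlation was best for 4 of 18 and 5 of 12 samples. Same-number values were -0.064 to 0.063 and -0.086 to 0.156, highest between UTX_FGFR3WT and UTX_FGFR3S249C replicates 3, so a shared batch is possible. Of 155 list calls among 384 list tests, 125 were lost with the estimated correlation. The filter at 5 CPM lost 18 list calls and gained 9. Without both libraries 3 list calls and 1 named-gene call were lost and 5 and 7 gained. With 1 library left out, which leaves fewer samples and changes the filtered genes, 29 named-gene calls and 32 list calls were lost and 2 and 51 gained.

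With each library left out in turn the counts ranged over 10371 to 10889 for UTX against EV in full medium, 8727 to 9176 in sphere medium, 2025 to 2464 with wild type FGFR3 and 3106 to 4479 with S249C. They ranged over 8523 to 8854 and 7187 to 7609 for HEAA in full and sphere medium, and 3031 to 3748 and 2914 to 3459 for UTX against HEAA. For the medium they were 12123 to 12441 in EV, 13131 to 13599 in UTX and 13119 to 13560 in HEAA. S249C gave 1124 to 1717 in EV and 291 to 535 in UTX. Interactions gave 6687 to 7149 for UTX by medium, 5842 to 6357 for HEAA by medium and 58 to 248 for UTX by FGFR3. The luminal p ranged over 0.216 to 0.39 for UTX in full medium, 0.00339 to 0.00715 in sphere medium, 0.523 to 0.628 with wild type FGFR3 and 2.83e-05 to 0.0015 with S249C, and over 0.00745 to 0.0132 for sphere medium in EV and 0.000696 to 0.00513 for S249C in EV. The correlation of the UTX effect in full medium ranged over -0.052 to -0.015 (lost) with the S249C effect and over 0.217 to 0.257 with the UTX effect beside wild type FGFR3. Depth and 3 libraries per group limit small changes: in simulated data changes of log2 0.5 were found in 73.1% and 64.2% of cases.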

Other observations

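No test in this part was chosen only after the result was seen. Lists not yet described for the medium moved as follows in UTX cells, sphere against full. Of the basal genes, 18 of 22 were higher and 4 lower (18 and 4 adjusted over the list alone, camera adjusted p = 3.1e-06, adjusted p = 0.0543 with an estimated correlation), of the squamous genes 19 of 20 were higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 4.46e-09, adjusted p = 0.0204 with an estimated correlation), and of the cholesterol synthesis genes 24 of 24 were higher and 0 lower (24 and 0 adjusted over the list alone, camera adjusted p = 2.41e-14, adjusted p = 0.0204 with an estimated correlation). In HEAA cells the squamous, FGFR and MAPK, cholesterol synthesis and YAP and TGF-beta lists passed both ways. In the squamous list 19 of 20 were higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 2.27e-09, adjusted p = 0.024 with an estimated correlation), and in the FGFR and MAPK list 20 of 26 were higher and 4 lower (20 and 4 adjusted over the list alone, camera adjusted p = 3.39e-06, adjusted p = 0.00691 with an estimated correlation). Of the cholesterol synthesis genes there, 24 of 24 were higher and 0 lower (24 and 0 adjusted over the list alone, camera adjusted p = 2.24e-14, adjusted p = 0.024 with an estimated correlation), and of the YAP and TGF-beta targets 2 of 20 were higher and 18 lower (2 and 18 adjusted over the list alone, camera adjusted p = 2.53e-11, adjusted p = 0.0264 with an estimated correlation). Basal genes passed with the preset correlation alone: 17 of 22 were higher and 4 lower (17 and 4 adjusted over the list alone, camera adjusted p = 5.07e-06, adjusted p = 0.0672 with an estimated correlation).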
